A study of Homo sapiens with 6 samples.

How the data were processed

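Total RNA was measured on 6 Affymetrix Human Genome U133 Plus 2.0 arrays, a platform on which each transcript is read by 1 or more probe sets of short oligonucleotides. The RNA came from HEK293 T-REx Flp-In cells, a human embryonic kidney line that carries a doxycycline-inducible copy of LIN28B with a FLAG/HA tag. Per the labels' protocols, 2 µg of total RNA per sample were labelled with biotin in a one-cycle assay. The labels put 2 arrays in each of 3 groups: mock transfected and not induced, mock transfected and induced, and transfected with siRNA against LIN28B. The labels do not say whether the numbered replicates came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. The labels' protocols give doxycycline at 250 ng/ml for 15 to 20 h before crosslinking. No time is given there for the cells whose RNA went onto the arrays.

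The values used are the authors' deposited log2 values per probe set. Per the submitters' processing notes they were made with affy and GCRMA, with versions not given in the sources used here. GCRMA corrects each array for background with a model of probe sequence, brings the arrays to a common distribution and summarises the probes of each set on the log2 scale. The base of the logarithm is not written in the file and was taken as 2, the base GCRMA returns. Values ran from 2.59 to 14.3, and the array medians lay between 7.126 and 7.177. The table holds 13008 probe sets, which is part of the array, and the rule that chose them is not given in the sources used here. A look at the table showed that 13007 of them lay above 5 on at least 2 arrays and 1 did not. A gene that was low on every array was therefore not analysed here. Genes low on the mock arrays are in the table mainly where the knockdown arrays read them higher. Of the genes tested, 101 were above 5 on both knockdown arrays and on no mock array. The table holds none of the array's control probe sets.

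Probe sets were named through the platform annotation supplied with the data, with symbols updated by gene identifier to the RefSeq table of assembly GRCh38.p14. Of the probe sets, 11719 had 1 gene symbol, 609 had several and 680 had none listed. Only those with 1 symbol were used for named genes. They stood for 11584 genes, of which 11578 matched the RefSeq table and 6 kept the annotation's symbol. For the 130 genes with more than 1 probe set, the set with the highest mean over all 6 arrays was used. Among these genes, 2 had probe sets called in opposite directions in the knockdown comparison, and 33 had some but not all of their probe sets called. Every other gene had a single probe set in the table. Agreement between probe sets could not be looked at for those genes, and averaging probe sets leaves their values unchanged. Since the rule that chose the probe sets is not given, whether differences between the arrays weighed in that choice is not known. The share of genes called and the sizes of change thus hold for the probe sets kept. Other probe sets of the same gene could read otherwise. A probe set ending in _x_at or _s_at can pick up related transcripts, and 3941 of the genes were read by one. Many list members named below were among them and are not each marked. A filter asked for a value above 4 on at least 2 of the 6 arrays and removed 0 probe sets. No coordinates are given, since the data files name no genome build.

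Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend) in 1 model of the 3 groups over all 6 arrays, so that 1 estimate of the spread served all comparisons. The model left 3 residual degrees of freedom, to which eBayes added 6.73 prior ones. Tests were two-sided moderated tests with Benjamini-Hochberg adjustment over all genes of a comparison, and a gene was called at an adjusted p under 0.05 with no fold minimum. The comparisons were knockdown against mock not induced, induced against not induced, and induced against knockdown. Errors given after ± are SDs over the 2 arrays of a group, and SE is the standard error of a fold change from the model. The number of arrays limits the precision of every value.

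Named genes followed a rule. For each comparison these were the 12 largest rises and the 12 largest falls among called genes whose groups did not overlap. Where fewer than 5 genes passed in a direction, the 5 of smallest unadjusted p were named as not passing. LIN28B was always named. LIN28A, its paralog, had no probe set in the table. From each gene list up to 4 called members of largest change in the knockdown comparison were named, or 2 members as values where none was called. The groups of every called gene were apart, which for 2 arrays against 2 is a weak demand. Further genes are said where they appear to be chosen after their values were seen.

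The 24 gene lists covered let-7 targets, mRNAs described as bound by LIN28 proteins, small RNA machinery, cell cycle, histones, ribosome, splicing, interferon and stress responses, p53 targets, metabolism, mitochondria, signalling, secretion, matrix and markers of other cell types. A list needed 5 members tested, which 22 lists had. Shifts were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 66 tests of 22 lists in 3 comparisons. Camera with an estimated correlation and fry were run beside it. The groups, tests, lists and naming rule were fixed before the data were examined.

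The procedure was tested on simulated data made from the means and spreads of the 11584 genes, with 10 repeats. In the simulated knockdown comparison 13.2% of genes changed by 0.25 on the log2 scale were called, 54.6% of those changed by 0.5, 97% at 1 and 100% at 2, and 7.35% of the calls were unchanged genes. In the simulated induction comparison these shares were 10.6%, 50.6%, 96.6% and 100%, with 7% of calls being unchanged genes. Only a small part of the genes was changed in each simulation, far fewer than the 3242 called in the real knockdown comparison. The share called depends on how many genes change, so these shares do not describe that comparison. Simulated lists of 30 genes shifted by 0.3 had a camera p under 0.05 in 100% of repeats, and unshifted lists in 2.5%. The simulated genes varied independently of each other, so these shares do not hold for lists whose members vary together.

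Alternatives were other scalings between arrays, other filters, other variance models, only the 4 arrays compared, the replicate number as a block, other ways to summarise a gene, other thresholds, and each array left out. A planned test of genes with let-7 sites in their 3′ untranslated regions was not run, because transcript sequences were not used here.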

Results

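The data are expression values of 11584 genes on 6 arrays of HEK293 cells, with 2 arrays in each of 3 groups. LIN28B is an RNA-binding protein that blocks maturation of the let-7 family of microRNAs and also binds many mRNAs. The study set out to measure how transcript levels change when LIN28B is depleted. The cells carried a tagged LIN28B gene that doxycycline switches on. Mock-transfected cells were measured without and with induction, and another group was transfected with siRNA against LIN28B. The arrays used here include no cells given a non-targeting siRNA, so the knockdown comparison holds siRNA transfection as well as the loss of LIN28B. Arrays of the same group correlated at r = 0.9899 to 0.9937 across probe sets, which are not independent replicates. Mock arrays with and without induction correlated at 0.9916 to 0.9935. The knockdown arrays correlated with the mock arrays at 0.97 to 0.9745.

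The targeted transcript was reduced in the cells given siRNA. LIN28B, read by a single probe set, had log2 values of 10.02 and 9.85 on the arrays of mock cells without induction and 7.51 and 7.53 on the knockdown arrays. The log2 fold change was -2.42 (SE 0.078, limma adjusted p = 5.02e-07), which leaves 18.7% of the mock level. It was the gene of smallest p in this comparison. On the induced arrays LIN28B read 10.15 and 10.11. The difference from the cells without induction was 0.19 (95% interval 0.02 to 0.37, limma adjusted p = 0.999) and did not pass. It was 0.28 without replicate 1 and 0.11 without replicate 2 of the cells not induced. The labels do not say whether the transgene carries the part of the transcript that this probe set reads, so the value does not check the induction.

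The first comparison asked which transcripts differ between LIN28B-depleted and mock-transfected cells. Next to LIN28B, the genes that fell most were GPAT3, an acyltransferase of triglyceride synthesis, the TNF receptor family member TNFRSF19, the mitochondrial ribosomal protein gene MRPL9 and KCTD12, an auxiliary subunit of GABA-B receptors. GPAT3 fell from 7.36 ± 0.14 to 5.17 ± 0.25 (SD, n = 2 each), a log2 fold change of -2.20. MRPL9 fell from 10.30 ± 0.01 to 8.18 ± 0.20 and KCTD12 from 9.90 ± 0.01 to 7.82 ± 0.07. The largest rise was in the histone H2B gene H2BC5, from 7.60 ± 0.10 to 9.77 ± 0.02. Chemokine genes rose with it, among them CXCL1 from 4.29 ± 0.11 to 6.45 ± 0.16 and CXCL10 from 3.31 ± 0.20 to 5.23 ± 0.15.

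The chemokines CXCL1, CXCL6, CXCL10, CXCL8 and CXCL2, which draw leukocytes to sites of inflammation, had log2 fold changes of 2.16, 1.94, 1.92, 1.66 and 1.62 with SEs between 0.21 and 0.27. All 5 had mean values under 5 in the mock cells without induction, in the lowest part of the scale, where background correction weighs most, and the table holds such genes mainly where the knockdown arrays read them higher. Other large rises were in ALDH8A1, an aldehyde dehydrogenase (2.16), the NOD-like receptor gene NLRP11 (2.08), the orphan receptor gene GPR19 (1.87), DKK3 of the dickkopf family (1.83), the cancer-testis antigen gene MAGEC2 (1.75) and BEX5 (1.63). Other large falls were in TNFRSF19 (-2.14), STOX1 (-1.97), TRIQK (-1.94), WIPF1, which binds the actin regulator WASP (-1.93), PTPMT1, a mitochondrial phosphatase of cardiolipin synthesis (-1.89), the antisense transcript THAP7-AS1 (-1.87), RFX3, a transcription factor of ciliated cells (-1.86), and the adhesion receptor gene ADGRG2 (-1.83). Of these 24 genes, CXCL2, CXCL8, H2BC5, GPAT3, MRPL9, TRIQK and MAGEC2 were read by probe sets that can pick up related transcripts. ALDH8A1, NLRP11, DKK3, MAGEC2 and BEX5 also had mean values under 5 in the mock cells without induction. TNFRSF19, STOX1, TRIQK, WIPF1, THAP7-AS1, RFX3 and ADGRG2 had mean values under 5 in the knockdown. The sizes and order of these changes thus rest on the lowest part of the scale too. The largest limma adjusted p among the 24 was 0.0042, for RFX3.

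In all, limma called 3242 of 11584 genes, or 28.0%, with 1563 higher and 1679 lower in the knockdown. Which direction held more genes depends on the scaling: with arrays centred on their medians 1835 were higher and 1524 lower. It also turned without replicate 1 of the mock cells not induced, with 1640 higher and 1503 lower. The median absolute log2 fold change of called genes was 0.489, and 105 rose and 150 fell by at least 2-fold. The number depends on the knockdown arrays: it was 1664 without replicate 1 and 1975 without replicate 2 of that group, where the lone array is assumed to vary like the others. It was 255 with a minimum of 2-fold.

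**Figure D1:**
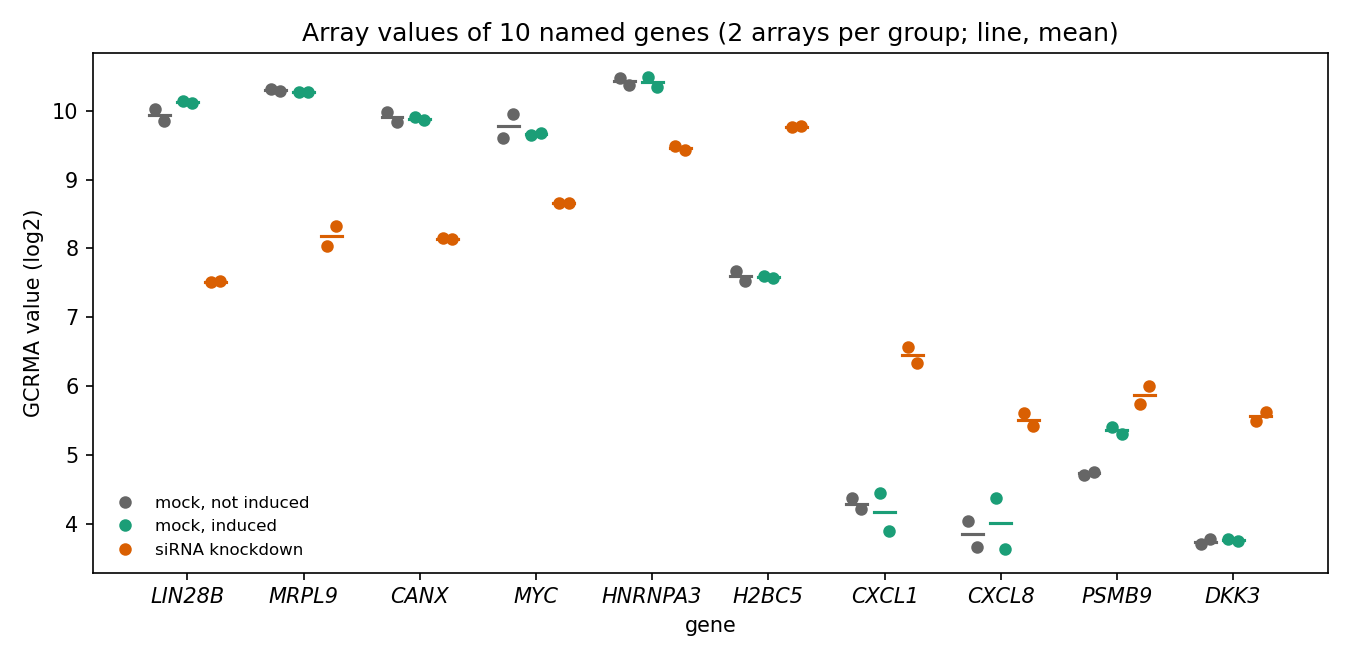
Log2 GCRMA values of 10 named genes on each of the 6 arrays, with points for arrays, colours for groups and short lines for the mean of 2 arrays. On the knockdown arrays LIN28B sits at 7.51 and 7.53, MRPL9 has a mean of 8.18 and H2BC5 one of 9.77, while the mock arrays with and without induction lie close together for most of these genes.

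Of the gene lists, splicing regulators and hnRNP genes were lower as a set in the knockdown. Of 38 members, 15 fell, 1 rose and 22 did not pass, and adjusted over the list alone 21 fell and 1 rose. The median log2 fold change was -0.22 (camera adjusted p = 0.00325, and adjusted p = 0.657 with an estimated correlation). HNRNPA3, which binds pre-mRNA, fell by 0.97 (SE 0.07), the SR protein gene SRSF11 by 0.55 and TARDBP, which encodes TDP-43, by 0.45. MBNL1, a regulator of alternative splicing, rose by 0.44.

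Histone genes were higher as a set, with 5 of 11 members up, 0 down and 6 not passing, and 6 up adjusted over the list alone. The median was 0.41 (camera adjusted p = 0.0105, and adjusted p = 0.657 with an estimated correlation). The estimated correlation between members was 0.443, far above the preset 0.01, so the call rests on a preset that these arrays go against. That correlation was 0.002 for splicing regulators and -0.011 for interferon response genes. Beside H2BC5, the linker histone gene H1-2 rose by 1.41 (SE 0.09), H2BC9 by 1.28 (SE 0.20) and H2AC6 by 0.88 (SE 0.14). Histone genes are close in sequence, so their probe sets may not be separate measurements.

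Interferon response genes were also higher as a set. Of 24 members, 7 rose, 0 fell and 17 did not pass, with 8 up adjusted over the list alone. The median was 0.30 (camera adjusted p = 0.0105, and adjusted p = 0.657 with an estimated correlation). The call was lost under the stricter filter on low values, with adjusted p = 0.0885. The interferon-inducible gene IFI27 rose by 1.23 (SE 0.20), the immunoproteasome subunit gene PSMB9 by 1.14 (SE 0.17), IFI35 by 0.79 and the antiviral membrane protein gene IFITM3 by 0.62. IFI35 and IFITM3 were read by probe sets that can pick up related transcripts.

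The lists closest to the known roles of LIN28 proteins did not pass by camera. Of 45 let-7 targets, 7 rose, 11 fell and 27 did not pass, with the same counts adjusted over the list alone. The median was -0.03 (95% interval -0.157 to 0.07 by resampling of members) and the camera adjusted p was 0.676. LIN28B is itself a member, and without it 7 rose and 10 fell of 44, and the camera p was 0.734, against 0.502 with it, neither adjusted. The transcription factor gene MYC fell by 1.13 (SE 0.10) and BACH1, a repressor of antioxidant genes, by 1.07 (SE 0.13), while LRIG3, a membrane protein gene, rose by 1.32 (SE 0.23). HMGA2, a chromatin protein gene often used as a let-7 reporter, had a log2 fold change of -0.13 (SE 0.08, limma adjusted p = 0.27). It was picked after its value was seen. Of 29 mRNAs described as bound by LIN28 proteins, 2 rose, 9 fell and 18 did not pass, and adjusted over the list alone 2 rose and 10 fell. LIN28B is 1 of these too, and 24 of the 29 are also in other lists. The median was -0.11 (95% interval -0.23 to -0.005 by resampling of members, camera adjusted p = 0.252, and adjusted p = 0.0105 by fry, which does not compare a list with other genes). Without LIN28B 2 rose and 8 fell of 28, and the camera p was 0.136, against 0.0572 with it, neither adjusted. The phosphofructokinase gene PFKP fell by 0.57 and the cyclin gene CCNA2 by 0.48. Of 21 genes of the small RNA machinery, 2 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.735). The RNA helicase gene DDX17 fell by 0.82, XPO5, which exports microRNA precursors, by 0.68, the uridylyltransferase gene TUT4 by 0.55 and KHSRP by 0.52.

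Cell cycle genes moved in both directions. Of 39 genes of S-phase entry and replication, 3 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.679). The thymidine kinase gene TK1 rose by 0.56, while MCM5 and MCM4, subunits of the replicative helicase, fell by 0.47 and 0.41. Of 38 genes of mitosis, 9 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.396). The proliferation marker gene MKI67 fell by 1.01 (SE 0.09), and TTK, NUF2 and CDK1 rose by 0.34, 0.32 and 0.32. Of 23 p53 targets, 8 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.409). The cell cycle inhibitor gene CDKN1A rose by 0.59, TP53INP1 by 0.98 and TP53I3 by 0.86, and the death receptor gene FAS fell by 0.61.

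Among genes of metabolism and protein synthesis, 12 of 31 glycolysis and hypoxia genes fell and 3 rose, or 15 and 5 adjusted over the list alone (camera adjusted p = 0.189). The hexokinase gene HK2 fell by 0.96, NDRG1 fell by 0.58, and the glucose transporter gene SLC2A3 and the mitophagy gene BNIP3L rose by 1.11 and 0.86. Of 22 genes of cholesterol and fatty acid synthesis, 5 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.396, and adjusted p = 0.0376 by fry). STARD4 and ELOVL6 fell by 0.60 each, the citrate lyase gene ACLY by 0.53 and DHCR7 by 0.52. Of 39 genes of the secretory pathway, 14 rose and 3 fell, or 16 and 3 adjusted over the list alone (median 0.14, camera adjusted p = 0.131). Its largest changes were falls, in the chaperone gene CANX (-1.77, SE 0.07) and in SSR1 (-0.90). SEC22B rose by 0.52 and SRPRA by 0.51. Of 40 genes of mitochondrial translation, 5 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.679). Beside MRPL9, MRPS9 fell by 0.68 and TSFM by 0.52, and MRPL1 rose by 0.40. Of 37 respiratory chain genes, 8 rose and 4 fell, or 8 and 5 adjusted over the list alone (camera adjusted p = 0.547). The cytochrome c gene CYCS fell by 0.69 and NDUFB10 by 0.34, and UQCRB and NDUFS4 rose by 0.40 and 0.37. Of 42 ribosomal protein genes, 4 rose and 4 fell, or 2 and 2 adjusted over the list alone (camera adjusted p = 0.826). RPL37 fell by 0.73, RPS24 fell by 0.30 and RPS23 rose by 0.36. RPS28 had a log2 fold change of -0.29 (adjusted p = 0.0404) and lay near the threshold. It lost its call when the arrays were centred (-0.26) or quantile normalized (-0.27), with only the 4 arrays compared (-0.29, adjusted p = 0.0777) and without either induced array (-0.29 in both).

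Among signalling and stress genes, 4 of 34 stress response genes rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.765). The ER chaperone gene DNAJB9 rose by 1.15, CREBRF rose by 0.92, the cystine transporter gene SLC7A11 fell by 0.79 and STC2 fell by 0.51. Of 26 immediate early genes, 5 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.785). IER3 rose by 1.31 (SE 0.09), the phosphatase gene DUSP6 by 1.02 and NR4A2 by 0.90. Of 28 insulin and mTOR signalling genes, 3 rose and 3 fell, or 2 and 1 adjusted over the list alone (camera adjusted p = 0.593). The kinase gene SGK1 rose by 0.71 and PIK3R3 by 0.52, while the receptor gene IGF1R fell by 0.57. IGF2R had a log2 fold change of -0.41 (adjusted p = 0.04) and lay near the threshold. It lost its call when the arrays were centred or quantile normalized (-0.38 in both), with only the 4 arrays compared (-0.41, adjusted p = 0.0578) and without either induced array (-0.41 in both). Of 31 TGF-beta and matrix genes, 6 rose and 10 fell, or 6 and 11 adjusted over the list alone (camera adjusted p = 0.593). ID1 and the collagen gene COL5A1 fell by 0.97 and 0.92, and the inhibitory SMAD gene SMAD7 and COL5A2 rose by 0.74 and 0.67. Of 14 neuronal and adrenal genes, 5 rose and 2 fell, or 6 and 3 adjusted over the list alone (camera adjusted p = 0.367). The RNA-binding protein gene ELAVL2 rose by 1.28, the granule protein gene CHGB by 0.98 and SYT1 by 0.75, and the adhesion molecule gene NCAM1 fell by 1.13.

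Marker lists of other cell types did not pass. Of 6 fibroblast markers, 0 rose and 1 fell, also adjusted over the list alone: VIM fell by 0.18 (camera adjusted p = 0.593). Of 6 epithelial markers, 2 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.563): KRT8 rose by 0.38, EPCAM rose by 0.28 and KRT19 fell by 0.59. Too few members of the other lists were in the table for a test. Of 3 pluripotency markers, KLF4 fell by 0.68, and of 2 blood cell markers, CD79A had 0.30 and HBB 0.12, neither passing.

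Some of these list members lost their call when 1 array of the compared groups was left out, with limma adjusted p between 0.0524 and 0.178. Without knockdown replicate 1 or 2 these were CCNA2, COL5A2, DHCR7, DNAJB9, ELOVL6, EPCAM, IGF1R, IGF2R, KHSRP, KRT19, KRT8, NR4A2, NUF2, RPS28, SEC22B, SGK1, SRPRA, STC2, SYT1, TSFM, TTK and VIM. ELOVL6 and KRT8 also lost it without replicate 1 of the mock cells not induced, and COL5A2, IGF1R, IGF2R, KHSRP, KRT19, RPS28, SEC22B, SYT1 and VIM without replicate 2. The fold changes of some members moved by more than 1.5 times with these mock arrays: without replicate 1 KRT8 had 0.24 and SEC22B 0.79, and without replicate 2 SEC22B had 0.26, KHSRP -0.33, SGK1 0.47 and TTK 0.22.

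**Figure D2:**
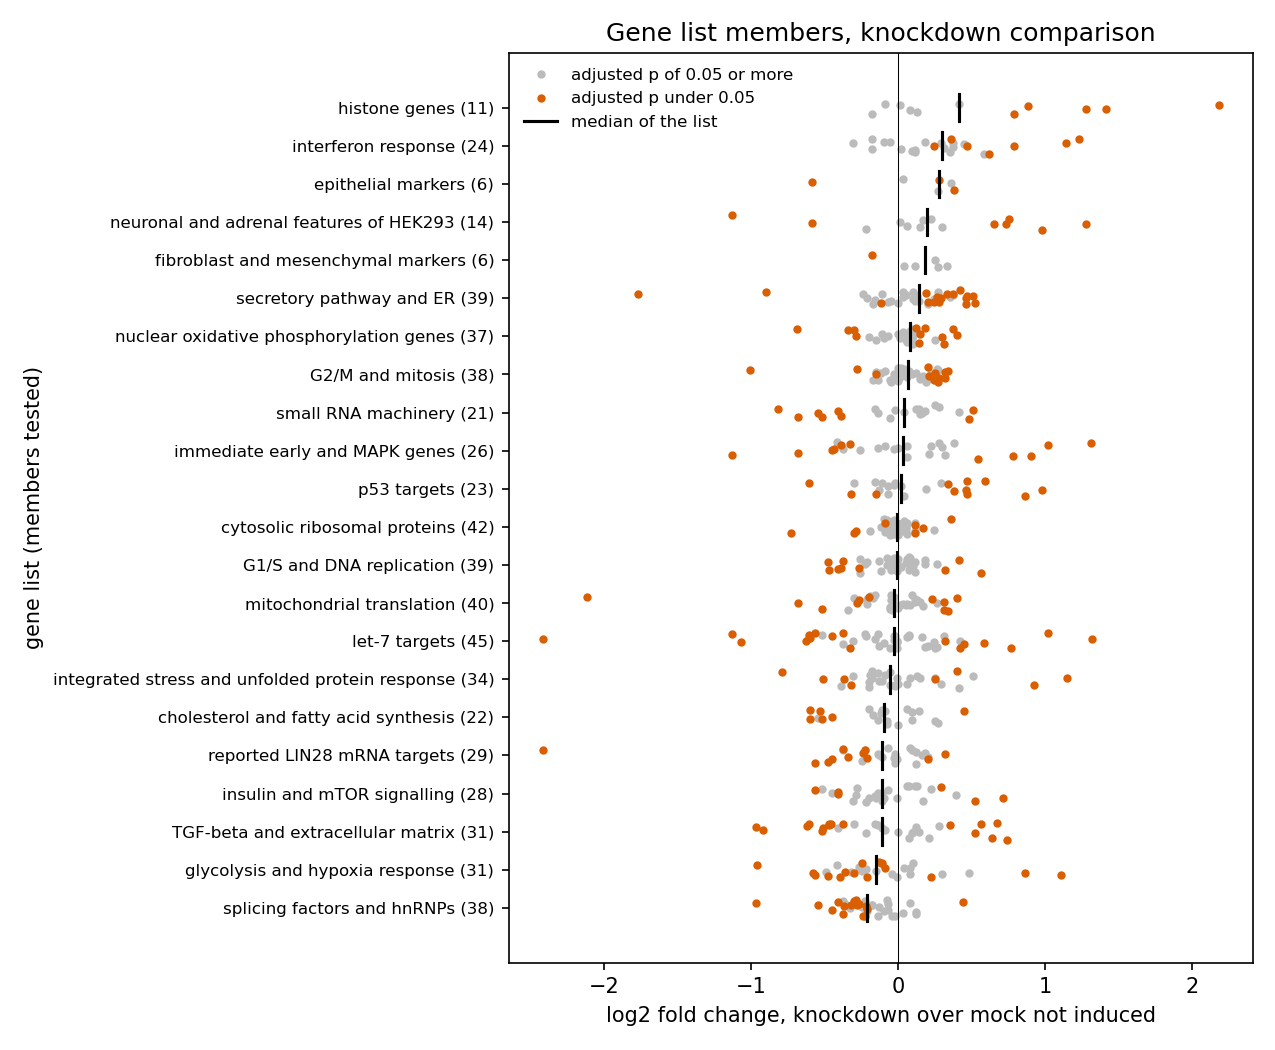
Log2 fold changes of the members of the 22 gene lists tested, knockdown over mock not induced, with 1 point per gene, colour for genes called at an adjusted p under 0.05 and black lines for list medians. The median is 0.41 for histone genes, 0.30 for interferon response genes, -0.03 for let-7 targets and -0.22 for splicing regulators.

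The second comparison asked what induction of the tagged LIN28B changes in mock-transfected cells. No gene passed. Limma called 0 of 11584 genes, and 344 had an unadjusted p under 0.05 where 579 were expected by chance. With the replicate number as a block 389 had such a p, and 0 were called. The observed number depends on the mock arrays not induced: it rose above the 579 expected by chance without either of them. There, again, the lone array is assumed to vary like the others. Genes of smallest unadjusted p, none of which passed, were the zinc finger gene ZNF320 (log2 fold change -1.01, SE 0.15, adjusted p = 0.764 by limma), HYCC2 (-0.71), FBXL14 (-0.40), KYNU (-1, SE 0.22) and the S6 kinase gene RPS6KB1 (-0.48) on the lower side. On the higher side they were the epoxide hydrolase gene EPHX2 (0.85, SE 0.15), the nuclear receptor gene NR0B2 (0.95), TIMP2 (0.58), ERC1 (0.55) and SLPI (0.83). None of the 22 lists passed at an adjusted p under 0.05. Let-7 targets had a median of 0.03 (camera adjusted p = 0.131), and the smallest adjusted p was 0.0768, for the stress response list, with a median of 0.05. With the replicate number as a block that list had adjusted p = 0.042. Mitosis genes had a median of -0.04 (camera adjusted p = 0.234), and adjusted p = 0.0315 without replicate 2 of the cells not induced. On data simulated for this comparison with few genes changed, 96.6% of genes changed by 1 on the log2 scale were called. The shares were 50.6% of those changed by 0.5 and 10.6% of those changed by 0.25. If as few genes changed in the cells, many changes of 0.5 or less would be missed.

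A further comparison set the induced cells against the knockdown, the highest against the lowest intended level of LIN28B, and it also holds siRNA transfection. LIN28B was higher in the induced cells by 2.61 (SE 0.078, limma adjusted p = 2.72e-07). The collagen IV gene COL4A3 was higher by 2.30, STOX1 by 2.20, WIPF1 by 2.16 and GPAT3 by 2.14. COL4A3, STOX1 and WIPF1 had mean values under 5 in the knockdown, in the lowest part of the scale. CXCL1 was lower in the induced cells, with a log2 fold change of -2.28, and H2BC5 had -2.18, NLRP11 -2.15 and GPR19 -2.09. CROT, a peroxisomal acyltransferase gene (-1.76), and the GABA transporter gene SLC6A13 (-1.66), the latter read by a probe set that can pick up related transcripts, were also among the largest differences. Of the 24 genes named for this comparison, 21 were also among the 24 named for the knockdown comparison.

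Limma called 3295 genes, 1679 higher and 1616 lower in the induced cells, or 1476 higher and 1910 lower with arrays centred on their medians and 1971 and 1984 with only the 4 arrays compared. The number fell to between 1702 and 2068 when either knockdown array or either induced array was left out: 1702 and 2068 without knockdown replicates 1 and 2, and 1928 and 1811 without induced replicates 1 and 2. Splicing regulators were higher in the induced cells, with 14 members up and 1 down of 38, also adjusted over the list alone (median 0.17, camera adjusted p = 0.0113). Histone genes were lower, with 6 of 11 down, or 7 adjusted over the list alone (median -0.68, camera adjusted p = 0.00325), and so were interferon response genes, with 6 of 24 down, or 4 adjusted over the list alone (median -0.26, camera adjusted p = 0.0223). With an estimated correlation each of these lists had an adjusted p = 0.657 by camera. For histone genes that correlation was again 0.443, above the preset 0.01. The splicing call was lost without knockdown replicate 2 (adjusted p = 0.0661). The interferon call was lost without induced replicate 2 (adjusted p = 0.0809), without knockdown replicate 1 (adjusted p = 0.0601) and under the stricter filter (adjusted p = 0.0902).

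Both comparisons with the knockdown use the same knockdown arrays. They shared 2712 called genes, of which 1410 were lower and 1302 higher in the knockdown, and 0 had opposite directions. These arrays are too few to split, so the overlap is no separate support for either comparison.

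A last question was whether knockdown and induction moved genes in opposite directions. Across the 11584 genes, which are not independent replicates, the log2 fold changes of the 2 comparisons correlated at Pearson r = 0.157 and Spearman rho = 0.155. Both are taken against the same mock arrays, which raises r, while the wider spread of the knockdown fold changes (SD 0.377, against 0.139 for induction) lowers it. The r was 0.347 without replicate 1 and 0.285 without replicate 2 of the cells not induced. The covariance was 0.00824, against 0.0116 (SD 0.000434) in 1000 simulations. The fold changes of induction had a variance of 0.0194, less than the 0.0232 that the replicate spread would give. The simulation thus gives them a wider spread than was observed, for a reason that was not tested. A share of 0.5 of the observed variance, the covariance expected with no effect of induction and equal spread in both mock groups, is 0.0097. The observed covariance was below that too. Replicates differed more in cells not induced than in induced cells (SD of the difference 0.246 against 0.191), which would place the expected covariance higher still. Genes do not vary independently, however, so the expected value has no known spread, and the direction of the 2 responses is left undecided.

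**Figure D3:**
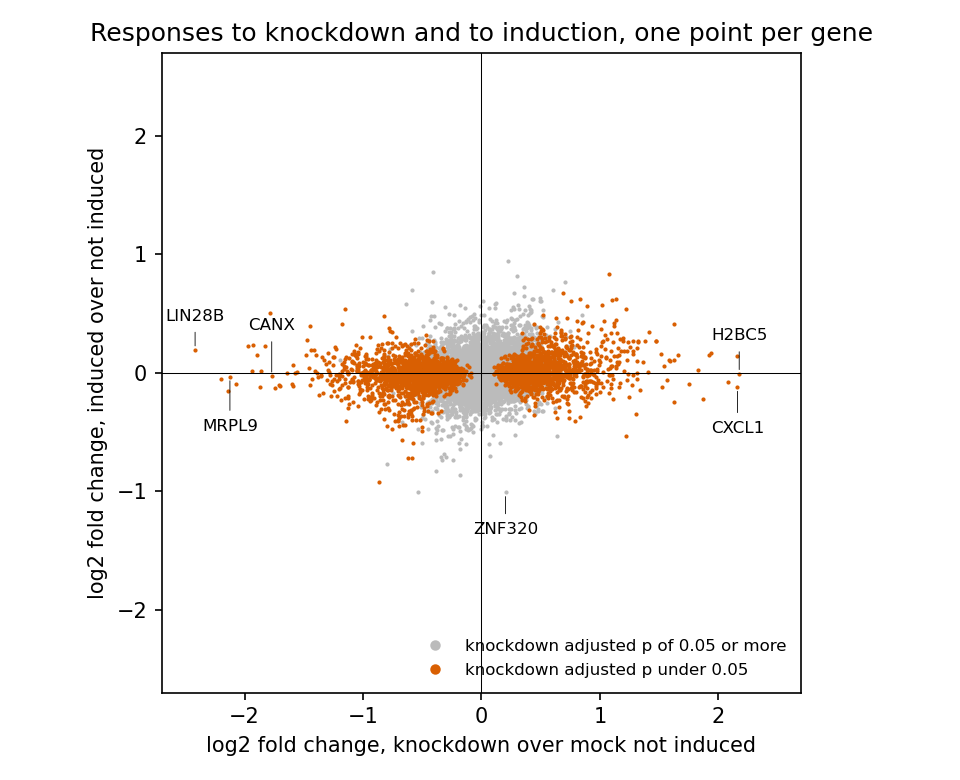
Log2 fold changes of each gene after knockdown (horizontal axis) and after induction (vertical axis), both over the mock cells without induction and drawn to the same scale, with colour for genes called in the knockdown comparison. Points spread along the horizontal axis to -2.42 for LIN28B and 2.18 for H2BC5, and the largest vertical value is the -1.01 of ZNF320.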

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

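Probe sets that the platform annotation gives no single gene were left out of the comparisons. Among these 1289 probe sets, 339 were called in the knockdown comparison when every probe set was tested with limma, with 148 higher and 191 lower. That is 26.3%, with 176 of them among sets with no gene listed and 163 among sets with several. Their log2 fold changes ran from -2.68 to 1.42. In the induction comparison 0 of them were called.

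The tests of a non-targeting siRNA, of opposite responses, of interferon genes and of let-7 targets, and the NF-kB list without CXCL3, were chosen after the results they bear on had been seen.

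The first pattern is that 3242 genes were called in the knockdown comparison, or 1664 and 1975 without knockdown replicates 1 and 2. An intensity-dependent difference between arrays would have shrunk that number under cyclic loess, but 3303 genes were called, 1.02 times as many, 3124 of them shared. That argues against such a difference left in the deposited values. With genes split by mean level into 5 groups, the median fold change was -0.014 to 0.027, so cyclic loess had little to remove. GCRMA had already brought the arrays to a common distribution, and a difference before that step was not tested. Transfected siRNA as such, or silencing of other transcripts by its sequence, stays open: the arrays used here include 0 of cells given a non-targeting siRNA, so it cannot be told apart from loss of LIN28B. Genes that follow LIN28B in both directions would give both responses a covariance below that of unchanged groups: 0.008236 was below the simulated 0.01158. The simulation, however, gives the induction fold changes a wider spread than was observed. A value taken as 0.5 times the variance of the induction response, 0.0097, also lies above it, and the wider replicate spread of cells not induced (SD 0.246 against 0.191) would raise that value, but it has no known spread, since genes do not vary independently, so this explanation also stays open.

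The second pattern is the rise of chemokine genes in the knockdown: of 8 chemokine genes in the table, 6 were called higher and 0 lower by limma, though genes this low enter the table mainly where they rose. A candidate explanation is a wider rise of NF-kB target genes: a list written after that rise was seen, without the 5 chemokines named for it but with CXCL3, had a median of 0.24 over 31 genes (camera p = 0.000158, and p = 0.023 with an estimated correlation), with 6 called higher and 2 lower. TNFAIP3 and NFKBIA, feedback inhibitors of NF-kB, rose by 1.10 and 0.83, while CD44 and KLF6 fell by 0.79 and 0.45, all 4 picked after their values were seen. Without CXCL3, which is 1 of the 6, the median was 0.23 over 30 genes with 5 higher and 2 lower (camera p = 0.000317, and p = 0.0264 with an estimated correlation), and without IRF1, PSMB9 and TAP1 of the interferon list as well it was 0.22 over 27 genes. CXCL3 and MMP9 of the NF-kB list and IFI27 of the interferon list lay above 5 on both knockdown arrays and on no mock array. The same selection by the table applies to them, and the NF-kB list was not tested under the stricter filter. An interferon response to transfected RNA is not settled, with a share of 0.292 of the tested interferon genes called higher, and neither result separates siRNA transfection from loss of LIN28B.

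The third pattern is that let-7 targets showed no net shift in the knockdown. LIN28B blocks let-7 maturation, so released let-7 may lower its targets, but the camera p of the list was 0.502, or 0.734 without LIN28B, the siRNA's own target. The interval of the median with LIN28B, -0.157 to 0.07, leaves room for a small fall. Of 44 members other than LIN28B, 10 fell, MYC and BACH1 among them, and 7 rose, LRIG3 among them, so members went both ways and the test decides neither way. By fry, which does not compare a list with other genes, the list with LIN28B had adjusted p = 0.0839 in the knockdown comparison. In induced against knockdown 12 members were higher and 7 lower in the induced cells (adjusted p = 0.0376 by fry, and camera adjusted p = 0.493). Levels of let-7 and a time after transfection were not used here.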

How the results depend on the processing

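The setting of cyclic loess between arrays was chosen after seeing the data. Under the 12 alternatives that kept the threshold and all replicates, or only the 4 arrays compared, the knockdown comparison gave 2129 to 3600 genes and induced against knockdown gave 2174 to 3955. The lowest values, 2129 and 2174, came without probe sets ending in _x_at or _s_at, where 7669 genes remained to test. A minimum of 2-fold gave 255 and 265. With each array left out the ranges were 1664 to 3143 and 1702 to 3951. The lower ends leave 1 array in an arm. The filter on low values removed no probe set, so leaving it out changes nothing by construction. The induction comparison kept 0 genes under every alternative that used all its arrays, with 239 to 446 genes at an unadjusted p under 0.05. With each array left out it gave 0 to 1 genes. The 1 gene was AKIRIN2 (log2 fold change -1.49, limma adjusted p = 0.002) without replicate 2 of the cells not induced, against -0.77 and adjusted p = 0.999 with all arrays. Its remaining array read 9.09, against 7.54 to 7.65 on the other 5, so the call rests on that lone array.

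LIN28B in the knockdown ranged from -2.50 to -2.33 with each array left out, past the threshold each time. The 48 named calls of largest change, of 27 distinct genes in 2 comparisons that share the knockdown arrays, all stayed called in the same direction under the alternatives run for them, from quantile normalization to each array left out. Neither the stricter filter nor the removal of probe sets ending in _x_at or _s_at was run for single genes. The stricter filter asks for a value above 6 on at least 2 arrays. It would remove some of these genes, such as CXCL10, CXCL8 and NLRP11, which lay under 6 on every array. Of 66 list tests, 6 were past the threshold, 5 to 7 with each array left out, 4 under the stricter filter and 0 with an estimated correlation, which is tested on 3 residual degrees of freedom. fry, which does not compare a list with other genes, called 10. The correlation of both responses ranged from 0.121 to 0.347 with each array left out, the 2 highest values being those without 1 of the mock arrays not induced, where the shared control weighs more. No named gene or list that was called turned to the other direction. The balance of calls did: with arrays centred on their medians the knockdown comparison gave 1835 higher and 1524 lower in place of 1563 and 1679, and induced against knockdown 1476 higher and 1910 lower in place of 1679 and 1616.

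The labels tie arrays of the same replicate number only by that number. Not induced and induced arrays of the same number correlated at 0.9935 for replicate 1 and 0.993 for replicate 2 across probe sets. Those of unlike number correlated at 0.992 and 0.9916. Within groups the values were 0.9899 for cells not induced and 0.9937 for induced cells. A block for the mock arrays alone was not tried. Differences between replicates 1 and 2 correlated across genes at 0.181 between not induced and induced cells, -0.057 between not induced and knockdown and 0.016 between induced and knockdown. With a replicate block the comparisons gave 3422, 0 and 3491 genes and 7 list tests. Signal over background limits genes near the lowest values, such as the chemokines.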

Other observations

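The tests in this part were chosen after the data were seen. Genes were grouped by the letters that open their symbols, and 77 such families had at least 15 genes tested. Genes whose symbol begins with ZNF, most of which encode zinc finger proteins, were higher in the knockdown. Of 330, 69 rose and 17 fell, with a median of 0.15 (camera adjusted p = 0.0218 over 231 tests, and adjusted p = 0.969 with an estimated correlation). The median was 0.15 to 0.18 under the scalings tried. Genes were split by mean level into 5 groups of equal size. In the 4 lower groups the ZNF median was 0.127 to 0.187, and in the highest group it was 0.239 from 15 genes. ZNF879 rose by 1.38 (SE 0.18), ZNF503 by 1.17 (SE 0.17) and ZNF559 by 1.09 (SE 0.11). The other family test that passed was of the same genes in induced cells against the same knockdown arrays, so it is no separate support (median -0.15, camera adjusted p = 0.0218, and adjusted p = 0.969 with an estimated correlation). No other family passed. The RAB family of membrane traffic GTPases came next in the knockdown comparison, with 14 of 51 higher and 3 lower (median 0.13, camera adjusted p = 0.373).

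Long non-coding RNAs made up 375 of the genes tested, and 59 were lower and 29 higher in the knockdown, or 23.5% in all, beside 28.2% of 11047 protein-coding genes. The share of genes called rose with level, from 15.7% in the lowest of the 5 groups to 43.9% in the highest, so these shares are not at matched levels.

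Of the genes tested, 101 lay above 5 on both knockdown arrays and on no mock array. Their direction is fixed by this choice. A further 161 lay at or under 5 on both knockdown arrays, also a choice made on those arrays. CD274, which encodes the immune checkpoint ligand PD-L1, was among the 101 with a log2 fold change of 1.58, and it was picked after its value was seen.

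PSMB9, also picked after its values were seen, read 4.73 ± 0.03 in mock cells without induction, 5.35 ± 0.08 with induction and 5.87 ± 0.19 in the knockdown (SD, n = 2 each). The difference on induction did not pass.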
